A study of Mus musculus with 6 samples.

How the data were processed

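Genomic DNA of LSK cells from mouse bone marrow was bisulfite-converted, amplified and sequenced by the study's authors, with 3 wild-type and 3 Tet1 knockout samples from mice 6 months old. The labels do not say whether the samples of a group came from separate mice. Bismark and the mouse build mm9 are named in the submitters' processing notes, without a role or version. The caller of differential methylation, its coverage minimum, its q-value threshold and the way replicates were combined are not given in the sources used here. The choice of an assay that enriches CpG-rich fragments limits the lists to such sequence.

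The 2 deposited tables list hypermethylated and hypomethylated cytosines. The authors' deposited value per cytosine is a methylation difference in percentage points, and the lists begin at 25 percentage points, per the file headers and the values themselves. The authors' other measurement is the distance in base pairs to the nearest annotated transcription start, beside a gene, a feature, a CpG island label and a repeat label. The number of columns of per-sample values was 0, so no sample means, replicate spread, coverage or per-site p-values were computed, and the depth per sample is unknown. The direction, knockout minus wild type, was taken from the list names and the signs. Each site is a single cytosine on 1 strand, and positions are those of the files (mm9). The sign of the distance followed the strand of the cytosine (386 of 386 opposite-strand pairs within 100 bp of each other and over 500 bp from a start had opposite signs), so absolute distances were used.

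Gene names are those of the files and mean the gene with the nearest transcription start, not a regulated gene. Entrez identifiers of 99.8% of sites were found in the RefSeq table for GRCm38.p6, which was used for names and gene order, never for positions. The names of 4 genes (15 sites) were stored as dates and were recovered from the identifiers as Septin9, Marchf4, Marchf5 and Marchf9.

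Sites of the same direction less than 1000 bp apart were joined into regions. A region took the commonest feature of its sites, with ties in the order promoter, exon, intron, intergenic, termination site; untranslated and non-coding exons counted as exons. Promoter sites lay up to 996 bp from a transcription start. Shares of features were compared between directions with Fisher's exact test, two-sided, and Benjamini-Hochberg adjustment over 5 features. The direction was tested with an exact two-sided sign test over 20 chromosomes, and medians with a two-sided permutation test (100000 permutations). Shares carry exact Clopper-Pearson intervals at 95%, which cover counting error only. The island comparison departs from its plan: the files give island labels to intron and intergenic sites alone, so regions of other features were left out of it. The planned test of replicate counts per site was not run.

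The tests, alternatives, named genes and 14 gene lists were fixed before the data were examined, except where the text says otherwise. Of the 777 list entries 775 were found in the reference. Each list was tested with Fisher's exact test, two-sided, against the other genes in the 2 tables, with adjustment over the 14 lists. Cytosines that were tested and not listed were not used here, so a list's share of listed genes also reflects how many of its cytosines were read. The named genes were the 10 with the most hypermethylated sites, the 5 with the most promoter hypermethylated sites outside those, the 5 with the most hypomethylated sites, up to 3 members per list with the most sites, and Tet1, Tet2, Tet3, Dnmt1, Dnmt3a and Dnmt3b. Of these genes, 1 is not reported here. Means and ranges given for a gene run over its listed sites and are not replicate errors; they exclude cytosines under 25 percentage points and so lie above the mean difference of the whole gene.

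The tests were tested on simulated data in 200 draws each. With no difference simulated, 7% of the Fisher tests on 4237 regions, 8% of the permutation tests of medians on 4237 regions and 4.5% of the gene list tests on 3344 genes fell under 0.05. A hypomethylated share of 0.3 times the hypermethylated share was found in 100% of draws, medians 3 percentage points apart in 96.5%, and a list of 84 genes with no hypomethylated member in 100%. Regions were simulated as independent, and the simulated median tests used fewer permutations than the analysis. Lists of fewer than 84 genes were not simulated, so these rates do not apply to them. In a single simulated set, the 200 planted clusters of 4 sites were all joined. Their spacing fixed that outcome, so it checks the code alone.

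Alternatives were an absolute difference of at least 40 percentage points, sites in place of regions or genes, joining within 200 or 5000 bp, autosomes alone and regions of at least 2 sites. Forward-strand sites alone, and the lists without the sites nearest G530011O06Rik, were added after the data were seen, as were 1000 random draws of 486 hypermethylated sites that compare spacing at equal list length. Analyses used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.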

Results

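Cytosine methylation was measured by enhanced reduced representation bisulfite sequencing, which samples mainly CpG-rich sequence, in LSK cells of mouse bone marrow. LSK cells lack lineage markers, carry Sca-1 and Kit, and contain the haematopoietic stem and progenitor cells. The cells were sorted from 6-month-old mice, with 3 wild-type samples and 3 samples from mice lacking Tet1, the gene of a dioxygenase that oxidises 5-methylcytosine. Bisulfite sequencing does not separate 5-methylcytosine from its hydroxymethyl form. The values analysed were those of the authors' deposited tables, which list single cytosines that differed between the genotypes by at least 25 percentage points, 1 difference per cytosine over all samples. Methylation levels, coverage and p-values per sample or site were not used here, so the depth behind each difference is unknown and the spread between replicates could not be set beside it. The differences are given as knockout minus wild type, a direction taken from the names of the lists and the signs in them, which could not be checked against group means.

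The first question was in which direction methylation differed in LSK cells without Tet1. Most listed cytosines were more methylated in the knockout: the authors' deposited tables held 6270 hypermethylated and 486 hypomethylated sites, a ratio of 12.9. Hypermethylated sites were thus 92.8% of the 6756 listed sites (exact Clopper-Pearson 95% interval 92.2 to 93.4%, counting error only). Sites less than 1000 bp apart were joined into 3786 hypermethylated and 451 hypomethylated regions, and 89.4% of the regions were hypermethylated (88.4 to 90.3%). Hypermethylated sites outnumbered hypomethylated sites on all 20 chromosomes, the 19 autosomes and X (exact sign test, two-sided, p = 1.91e-06). The chromosomes come from the same 6 samples and are not replicates. A shift common to the whole genome, whatever its source, would place them all on the same side. The nearest genes numbered 3344, of which 2910 had hypermethylated sites alone, 434 had a hypomethylated site and 108 had both.

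Hypermethylated sites also differed by more. The authors' deposited table gave hypermethylated sites a median difference of 41.1 percentage points (range 25.0 to 97.6) and hypomethylated sites a median of -34.1 percentage points (range -86.9 to -25.1). Per region, the median absolute difference was 39.3 percentage points for hypermethylated and 34.0 percentage points for hypomethylated regions, a gap of 5.31 percentage points (permutation test, two-sided, p = 1e-05, the smallest that 100000 permutations can give). With regions of at least 2 sites alone the gap was 5.50 percentage points and did not pass (permutation p = 0.104), with 15 hypomethylated regions left. At an absolute difference of at least 60 percentage points, the lists held 770 hypermethylated and 14 hypomethylated sites. At least 2 sites were held by 1205 hypermethylated regions (31.8%) and 15 hypomethylated regions (3.33%). When 486 hypermethylated sites were drawn at random 1000 times, to match the shorter list, a median of 5.92% of the regions held at least 2 sites (95% of draws between 3.85 and 8.07%). The share was at or below 3.33% in 7 of the draws. Drawing single sites breaks up clusters by itself, so the fall from 31.8% does not measure an effect of list length. Neighbouring sites and regions are not independent replicates, so these tests describe the lists and not the spread between mice.

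The genes nearest to the most hypermethylated sites carried them in promoters, exons, introns and intergenic sequence. Plekhh3, which encodes a pleckstrin homology domain protein, had 17 sites in the authors' deposited table, at chromosome 11, 101025463 to 101029412 (mm9), all in exons 4, 5, 7 and 11 of 13, with a mean difference of 42.7 percentage points (range 27.8 to 58.5 over sites). Comp, the gene of cartilage oligomeric matrix protein, had 15 sites in a single region at chromosome 8, 72900111 to 72901075, 14 of them in exons 7, 9 and 10 of 19. Their mean difference in the authors' deposited table was 44.0 percentage points. Gm5294 had the highest mean of the 10 genes with the most sites: its 13 sites at chromosome 5, 139297159 to 139297342, in intron 2 and exon 3, averaged 76.5 percentage points in the authors' deposited table and reached 96.2. All 12 sites of Kcng4, a potassium channel subunit gene, lay in exon 2 of 3 at chromosome 8, 122156894 to 122157265, with listed differences from 25.8 to 86.5 percentage points. Prss56, a serine protease gene, had 12 sites on chromosome 1 between 89067002 and 89081409, 6 of them in exon 4 of 13, with a listed mean of 54.7 percentage points. Gm10421 had 14 sites averaging 38.1 percentage points in the authors' deposited table, 13 of them in introns of the gene annotated over that stretch of chromosome 12.

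Among hypomethylated sites, 1 gene had at least 5 of them. That gene was G530011O06Rik on the X chromosome (166428075 to 166436039), with 18 hypomethylated sites averaging -34.2 percentage points in the authors' deposited table, all 11226 to 19190 bp from its transcription start. Of these 18 sites, 13 lay in an intergenic CpG island and 5 in the 3′ UTR of another transcript. Ammecr1, also on X, had 4 hypomethylated promoter sites 17 to 67 bp from its transcription start (139401288 to 139401338), with a listed mean of -42.9 percentage points. Akap6, the gene of a protein kinase A anchoring protein, had 4 hypomethylated sites in introns 1, 2 and 3 on chromosome 12, with a listed mean of -53.5 percentage points, and 1 hypermethylated site (32.4 percentage points) in intron 5. The 4 sites nearest Sfswap, a splicing regulator gene, lay in an intergenic LINE repeat at chromosome 5, 129969620 to 129969645, and averaged -43.2 percentage points in the authors' deposited table. Rn45s had 3 hypomethylated sites (mean -56.8 percentage points) and 1 hypermethylated site, values that are uncertain because ribosomal RNA genes occur in many near-identical copies.

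**Figure D1:**
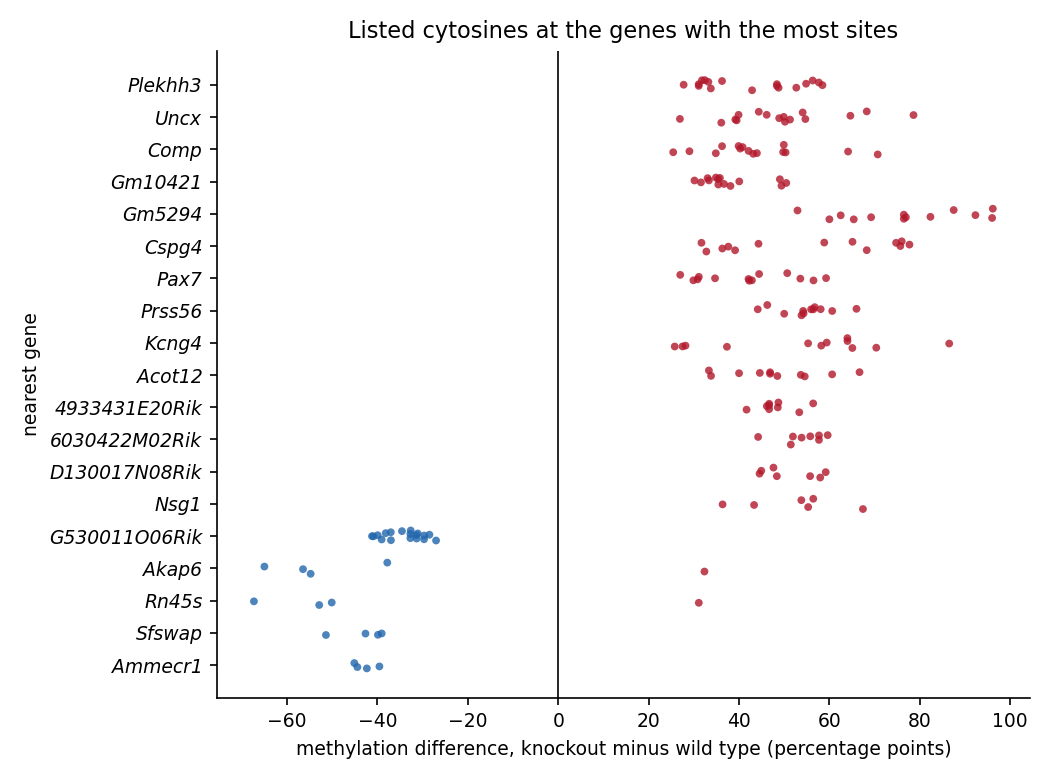
Methylation difference (knockout minus wild type, percentage points) of each listed cytosine, a point each, at the genes with the most hypermethylated, promoter hypermethylated and hypomethylated sites. The plot leaves out 1 gene that is not reported here, and vertical jitter carries no value; no point lies between -25 and 25 because the deposited lists start there, and the 13 points of Gm5294 reach 96.2.

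The second question was where the gains and losses lay. Promoters made up 408 of the 3786 hypermethylated regions (10.8%, exact interval 9.81 to 11.8%) and 17 of the 451 hypomethylated regions (3.77%, 2.21 to 5.97%), a difference of 7.01 percentage points (Fisher's exact test, two-sided, p = 3.11e-07, adjusted p = 1.55e-06 over 5 features). Of the 17 hypomethylated promoter regions 8 lay on X, and among regions of at least 2 sites the difference was -1.30 percentage points (Fisher's exact p = 0.700). The exon share was 14.6% against 13.1% and the intron share 34.3% against 39.0% (Fisher's exact test, adjusted p = 0.544 and 0.132). The intergenic share was 38.5% against 42.4% and the share at transcription termination sites 1.85% against 1.77% (adjusted p = 0.189 and 1 by the same exact test). Counted by site, the differences in the exon, intron and intergenic shares were 5.97, -5.35 and -7.48 percentage points and passed (Fisher's exact test, adjusted p = 0.00207, 0.0216 and 0.00207), although neighbouring sites are not independent. Within 5000 bp of a transcription start lay 1602 of the 3786 hypermethylated regions and 81 of the 451 hypomethylated regions (odds ratio 3.35, Fisher's exact p = 1.37e-25). The wild-type level of a site limits the direction in which it can be listed, and such levels were not used here. The promoter and distance comparisons therefore describe the lists and do not show where the loss of Tet1 acts.

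Promoter hypermethylation reached clusters of sites at single genes. Acot12, an acyl-CoA thioesterase gene, had 11 promoter sites in the authors' deposited table at chromosome 13, 91880797 to 91881156, with a mean difference of 48.1 percentage points (range 33.3 to 66.7). Cspg4, the gene of the proteoglycan NG2, had 9 promoter sites on chromosome 9 averaging 64.4 percentage points in the authors' deposited table, and 4 sites in exons 3 and 4 of 10. The genes 4933431E20Rik, on chromosome 3, and 6030422M02Rik, on chromosome 1, had 8 promoter sites each, with listed means of 49.1 and 54.0 percentage points. D130017N08Rik had 7 and Nsg1, a neuronal vesicle trafficking gene, had 6 promoter sites on chromosome 5, with means of 51.2 and 52.1 percentage points in the authors' deposited table. The promoter sites of Acot12, 6030422M02Rik, D130017N08Rik and Nsg1 each lay on a single strand. Close sites on the same strand may share reads, so the site counts are not counts of independent measurements.

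CpG island labels in the files cover intron and intergenic sites, so islands were compared among regions of those kinds. Island regions were 123 of 2756 hypermethylated (4.46%, exact interval 3.72 to 5.30%) and 6 of 367 hypomethylated regions (1.63%, 0.602 to 3.52%), a difference of 2.83 percentage points (Fisher's exact test, two-sided, p = 0.00754). The difference did not pass at 40 percentage points or over single sites (Fisher's exact p = 0.123 and 0.189), and it was -3.71 percentage points among regions of at least 2 sites (Fisher's exact p = 0.483). The limit that the wild-type level sets on direction applies to islands too. Cdkn1c, a cyclin-dependent kinase inhibitor gene in the stem cell, cell cycle and imprinted lists, had 7 of its 9 intergenic hypermethylated sites in islands, and the 9 averaged 37.9 percentage points in the authors' deposited table.

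**Figure D2:**
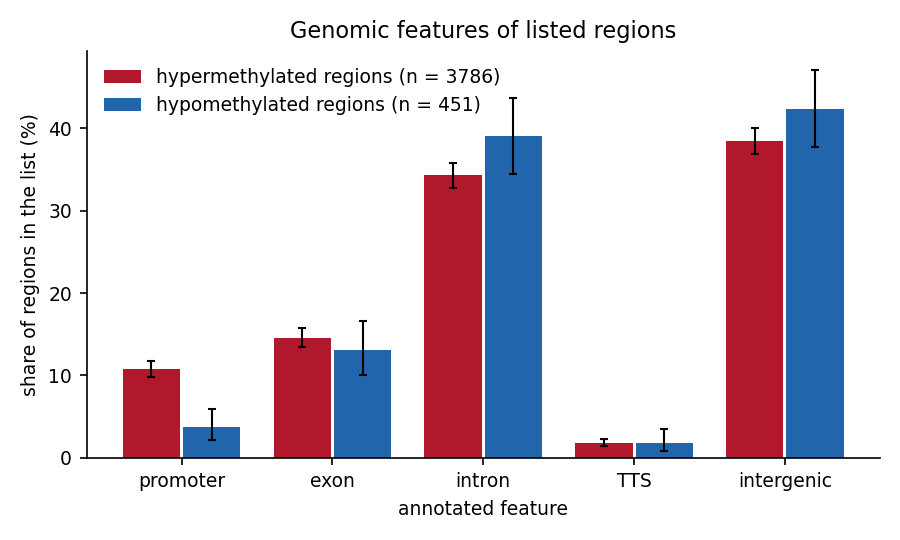
Share of regions (%) in each annotated feature, for 3786 hypermethylated and 451 hypomethylated regions, with exact 95% intervals as error bars; TTS is the transcription termination site. The promoter shares are 10.8% and 3.77%, and the intervals of each other feature overlap.

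The third question was whether genes of particular functions differed in direction. For 14 lists fixed before the data were examined, members with hypermethylated sites alone were set against members with any hypomethylated site, relative to all other genes in the authors' deposited tables. No list differed after adjustment over the 14 lists, and 1 did at an unadjusted p under 0.05 (Fisher's exact test, two-sided). Short lists could not pass in the hypermethylated direction: with all 9 listed erythroid and megakaryocyte genes hypermethylated alone, p was 0.615 by Fisher's exact test, since 87.0% of the other genes were too. That list was developmental transcription factors: 84 of its 165 members were nearest to a listed site, 79 of them (94.0%) with hypermethylated sites alone, against 86.8% of the other genes (odds ratio 2.39, Fisher's exact p = 0.0491, adjusted p = 0.687). The unadjusted p of this list was 0.0664 on autosomes, 0.0677 without the sites nearest G530011O06Rik, 0.0560 on the forward strand, 0.767 at 40 percentage points and 1 with regions of at least 2 sites (Fisher's exact test), so that call was lost. Counted by site rather than by gene, this list passed (adjusted p = 0.0150 by Fisher's exact test), although sites within a gene are not independent. Uncx, a homeobox gene of the paraxial mesoderm, had 16 intergenic sites 11503 to 49933 bp from its start on chromosome 5, averaging 49.5 percentage points in the authors' deposited table. Pax7, a regulator of muscle stem cells, had 13 sites on chromosome 4 (mean 41.9 percentage points), and Lhx5, a LIM homeobox gene, had 12 on chromosome 5 (mean 46.2 percentage points in the authors' deposited table). The 5 members with a hypomethylated site, named after their values were seen, were Dlx1, Hand2, Hoxd1, Irx6 and Twist1, and Hoxd1 and Irx6 had hypermethylated sites too.

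Genes of signalling pathways (Wnt, Notch, TGF-β and Hedgehog) were the next most often listed, with 30 of 83 members, 25 of them with hypermethylated sites alone. Bmp7, a secreted TGF-β family ligand, had 8 hypermethylated sites with a mean of 59.6 percentage points. Of these, 7 were intergenic, and the farthest lay 152755 bp from its start. Wnt7b had 7 sites with a mean of 45.3 percentage points. The signal transducer Smad3 had 5 with a mean of 61.5 percentage points in the authors' deposited table, 119217 to 122791 bp from the gene's start. The 5 members with a hypomethylated site were Fzd10, Ihh, Jag2, Smad1 and Smad7, named after their values were seen.

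Among blood cell genes, 9 of 31 erythroid and megakaryocyte genes were listed, all 9 with hypermethylated sites alone. Trim58, an erythroid ubiquitin ligase gene, had 5 sites in exon 1 and intron 1 at chromosome 11, 58454180 to 58454618 (mean 62.0 percentage points in the authors' deposited table). The platelet glycoprotein gene Gp1bb was nearest to 5 sites (mean 51.0 percentage points), 1718 to 2438 bp from its start. Those 5 lay in exons 5, 7 and 8 and intron 5 of another transcript. The red cell membrane gene Ank1 had 4 sites (mean 52.2 percentage points). Of 34 B-lymphoid genes, 8 were listed, all with hypermethylated sites alone. They included Pax5, which maintains B cell identity, with 1 promoter and 4 intronic sites averaging 36.9 percentage points in the authors' deposited table. Lef1 had 4 sites (mean 53.8 percentage points), 3 of them intergenic at 91024 to 187040 bp from its start. Irf8 had 4 sites (mean 31.2 percentage points), 3 intronic and 1 intergenic at 149915 bp. Of 31 T and natural killer cell genes, 8 were listed and 7 had hypermethylated sites alone. Runx3, a regulator of cytotoxic T cells, had 4 hypermethylated sites in exon 3 of 6 (mean 44.9 percentage points) and 1 intergenic hypomethylated site (-38.5 percentage points) in the authors' deposited tables. Thy1 had 3 intergenic sites at least 108791 bp from its start (mean 64.2), and Bcl11b, required for T cell commitment, had 3 intronic sites (mean 48.0 percentage points). Of 30 myeloid genes, 7 were listed and 6 had hypermethylated sites alone; the other was Csf2ra, a subunit of the GM-CSF receptor, with 2 hypomethylated sites in exon 6 of 12 (mean -38.3 percentage points). Fcgr3 had 2 hypermethylated intergenic sites and Mmp9 had 1 intronic site, at 37.4 and 44.9 percentage points in the authors' deposited table.

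Genes of stem cell identity were listed for 5 of 38 members, with 4 hypermethylated alone. Hlf, a transcription factor of haematopoietic stem cells, had 2 sites in intron 2 of 3 (mean 48.5 percentage points in the authors' deposited table), and Mecom, another such factor, had 1 hypomethylated intronic site at -40.0 percentage points. Of 59 genes of blood cancers, 11 were listed and 10 had hypermethylated sites alone; the apoptosis inhibitor Bcl2 had 5 sites in exon 1 of 2 at chromosome 1, 108609270 to 108609424 (mean 39.7 percentage points). Of 49 cell cycle genes 4 were listed, all hypermethylated alone, among them Mycn with 4 sites at least 216613 bp away (mean 51.5 percentage points). Cdk6 was nearest to 3 sites, all in a LINE repeat 150483 to 150499 bp away (mean 34.4 percentage points in the authors' deposited table). DNA repair genes were listed for 4 of 86 members, all hypermethylated alone, namely Ercc6, Exo1, Smug1 and 1 other, with means of 36.9, 35.4 and 55.7 percentage points for the named genes.

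Imprinted genes were listed for 9 of 52 members, 8 with hypermethylated sites alone, such as Rasgrf1 (2 sites, mean 46.5) and Nap1l5 (2 sites, mean 39.8 percentage points in the authors' deposited table). Clustered protocadherin genes were listed for 9 of 58 members, all hypermethylated alone. Pcdhac1 had 9 sites (mean 46.2), Pcdhac2 6 (mean 45.2) and Pcdhga1 4 (mean 53.3 percentage points), values that are uncertain because these genes resemble one another. Markers of stromal and endothelial cells were listed for 7 of 30 members, 5 with hypermethylated sites alone and 2, Runx2 and Sparc, with a hypomethylated site (Fisher's exact p = 0.227, adjusted p = 1). The purity of the sorted cells was not examined. Col1a1, a collagen gene, had 8 hypermethylated sites averaging 41.8, Alpl had 1 at 44.3 and Pdgfrb 1 at 41.2 percentage points in the authors' deposited table. Adjusted p was 1 by Fisher's exact test for each list other than the developmental transcription factors.

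The targeted gene and the related enzymes were nearest to few listed sites. Tet1, Tet3, Dnmt1 and Dnmt3a had 0 listed sites. Tet2 had 1 hypermethylated intergenic site 210226 bp away (30.1 percentage points at chromosome 3, 133417580), and the de novo methyltransferase gene Dnmt3b had 1 in intron 2 of 22 (51.5 percentage points at chromosome 2, 153476748) in the authors' deposited table. These counts do not check the deletion, since a list of differing cytosines does not measure it. Of the 29 genes of the methylation machinery 6 were listed, all hypermethylated alone. Among them, Cxxc4 had 4 sites 46381 to 46476 bp away (mean 39.9 percentage points). Gadd45g had 1 site 123014 bp away (42.1 percentage points).

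**Figure D3:**
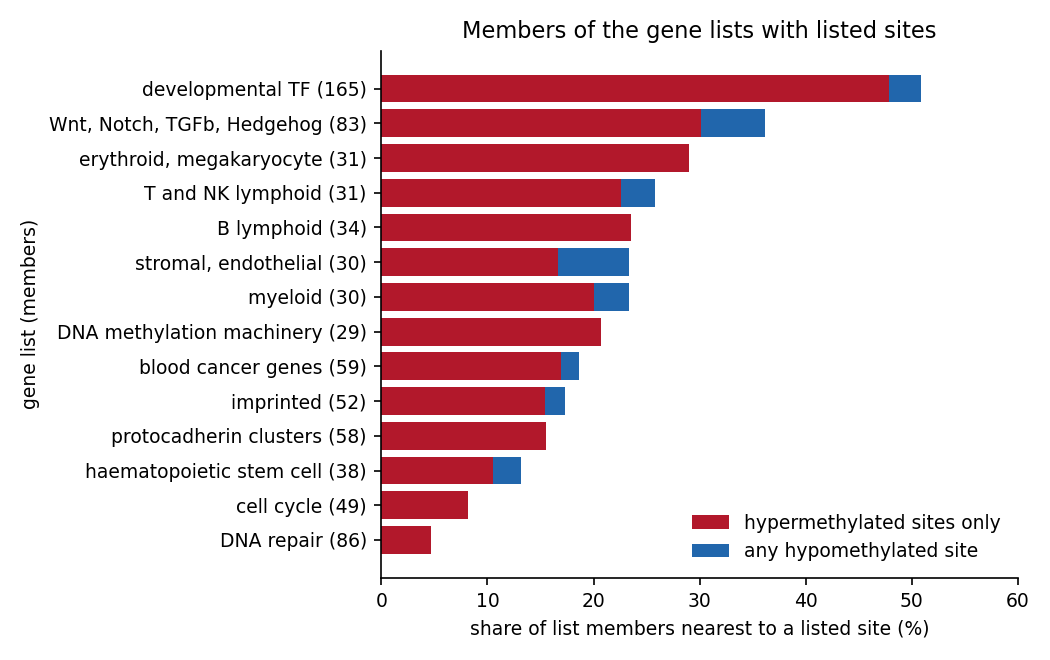
Share of each gene list's members (%) that were nearest to a listed site, split into members with hypermethylated sites alone and members with any hypomethylated site; the number of members is in parentheses. Developmental transcription factors, with 79 and 5 of 165 members, have the longest bar.

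**Figure D4:**
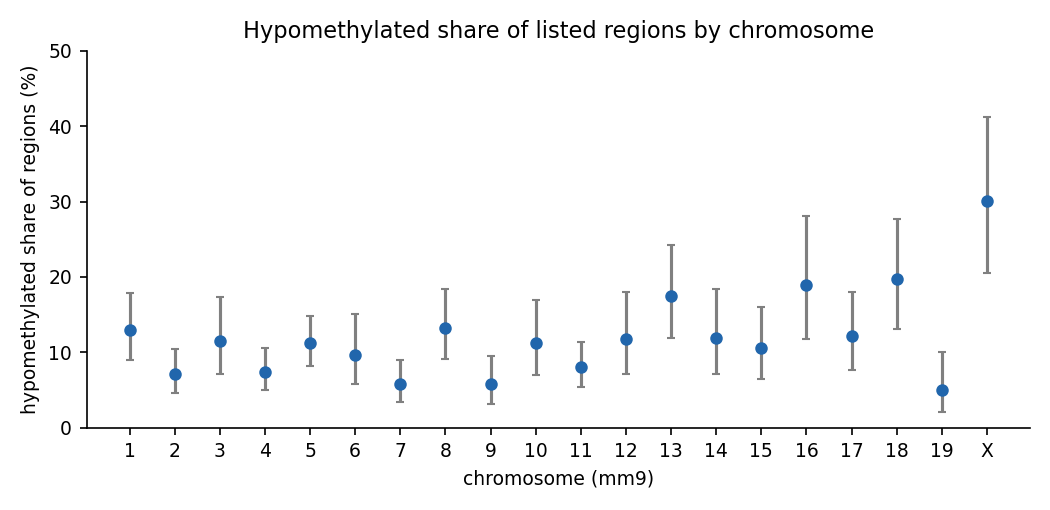
Hypomethylated share of listed regions (%) on each chromosome (mm9), with exact 95% intervals that cover counting error only. The autosomes lie between 5.04% and 19.7% and X lies at 30.1%.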

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

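The tests in this part were chosen after the results were seen, except that of sites near transcription starts at developmental genes.

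Annotated repeats held 554 of the listed sites, 446 hypermethylated and 108 hypomethylated, and stood out because the planned comparisons did not use the repeat labels. Among intron and intergenic regions, repeats held 103 of 367 hypomethylated regions (28.1%, exact interval 23.5 to 33.0%) and 321 of 2756 hypermethylated regions (11.6%, 10.5 to 12.9%), by Fisher's exact test p = 4.26e-15 (adjusted p = 1.71e-14 over 4 comparisons). LTR elements held 10.6% against 4.61%, LINE elements 7.08% against 2.36% and SINE elements 8.17% against 3.74% of these regions (adjusted p = 1.40e-05, 1.40e-05 and 0.000281 by Fisher's exact test). The wild-type level of a site limits the direction in which it can be listed, and such levels were not used here.

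The excess of hypermethylated sites was weighed first. A signal from 1 bisulfite strand alone would place most sites on that strand, and 50.0% of hypermethylated sites (50.0319%) lay on the forward strand, which argues against it. A difference in depth between the groups, the authors' filters and incomplete conversion were not tested, because neither coverage nor per-sample levels were used here. The knockout of Tet1, an enzyme that oxidises methylated cytosine, may account for the excess as a hypothesis, and in these lists it cannot be separated from the untested explanations.

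Hypomethylated regions were more frequent on X, 25 of 83 (30.1%, exact interval 20.5 to 41.2%), than on the autosomes, 426 of 4149 (10.3%, 9.36 to 11.2%), with Fisher's exact p = 7.56e-07. Among promoter regions the share was 8 of 22 on X (36.4%) and 9 of 403 on autosomes (2.23%), Fisher's exact p = 2.39e-07; the 8 lay at Timm17b, Fhl1, Fgf13, Mtcp1, Ercc6l, Ammecr1, Klf8 and Mid1, and the 14 hypermethylated ones included Pdha1, Rps4x and Syap1. By site the X share was 35.4% (46 of 130) and, without the 18 sites nearest G530011O06Rik, 25.0% (28 of 112), against 6.65% on autosomes (Fisher's exact p = 1.40e-09 without that locus), so that locus supplies part of the excess by site but not the whole. A different mix of sexes in the groups could move X promoters and distal X sequence in opposite directions. Regions outside promoters had a higher hypomethylated share on X too (27.9% against 11.1%, Fisher's exact p = 0.000307). They include sequence close to transcription starts and the regions nearest G530011O06Rik, so this comparison cannot decide about the sexes. Farther than 5000 bp from a start, where the G530011O06Rik regions also lie, the shares were 26.5% and 14.4% (Fisher's exact p = 0.0799). The labels give no sex, so a different mix of sexes cannot be told apart from an effect of genotype. The wild-type level of a site also limits its direction. Such levels were not compared between X and the autosomes, so the excess on X may have that source too. The distal test replaced a first one, on whether X promoters moved both ways. Gains on X promoters are also what the genome-wide excess would give, so that first test was set aside.

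Developmental transcription factor genes were often nearest to a hypermethylated site, 81 of 165 (49.1%), against 101 of 585 members of the other lists (17.3%; Fisher's exact p = 1.33e-15). Long intergenic stretches around these genes would remove the excess once distant sites are left out, yet within 5000 bp of a transcription start the shares were 23.6% and 8.89% (Fisher's exact p = 2.42e-06). The coverage of the assay, which favours the CpG-rich sequence of such genes, may still be the source: their share was 2.71% of the genes with hypermethylated sites alone and 1.15% of those with a hypomethylated site, with Fisher's exact p = 0.687 adjusted over the 14 lists and 0.0491 unadjusted. An earlier version of that test used the unadjusted value, by which coverage would have been excluded, and the adjusted value was put in its place after both were known; the unadjusted value was 0.0677 without the sites nearest G530011O06Rik and 0.0664 on autosomes. Coverage and an effect of the knockout cannot be told apart here, because the cytosines that were read and not listed were not used.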

How the results depend on the processing

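Forward-strand sites and the lists without G530011O06Rik were alternatives chosen after the data were seen. Over 8 alternatives the hypermethylated share ranged from 88.9 to 98.7% (exact sign test p at most 3.81e-06 for each). Of the 38 alternative values of the 5 main results, 32 kept their direction and their side of the threshold. With an absolute difference of at least 40 percentage points, the island difference was 3.31 (Fisher's exact p = 0.123, with 1 hypomethylated island region); over sites it was 1.75 percentage points (p = 0.189, exact). With regions of at least 2 sites, which left 15 hypomethylated regions, the promoter difference was -1.30 (2 hypomethylated regions, both on X), the island difference -3.71, the intron difference 14.5 and the gap between medians 5.50 percentage points (permutation p = 0.104). Counted by site, 1 of 14 lists passed in place of 0. Apart from these, promoter differences reached 8.47 percentage points and the gap between medians ran from 2.91 to 6.96.

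Among the feature and list values, judged by p adjusted over 5 features or 14 lists, 95 kept direction and side, 6 newly passed and 15 reversed; the cause was not tested. Those that newly passed were the exon, intron and intergenic shares and the developmental list by site, the intergenic share at 40 percentage points (-10.6) and the intron share on the forward strand (-9.94). The termination site difference was -0.223 at 40 percentage points, -0.197 with 5000 bp joins, -0.0246 on autosomes and -1.42 on the forward strand. Differences in the share of members hypermethylated alone reversed as follows, in percentage points. At 40 percentage points they were 7.13 (myeloid) and 7.19 (signalling), and by site 0.0509 (stem cell). With regions of at least 2 sites they were 1.25 (stem cell), 1.26 (signalling) and 1.25 (stromal). On the forward strand they were 12.1 (stem cell), -7.90 (imprinted), 12.1 (myeloid) and 5.02 (signalling). Each such list had at most 5 members with a hypomethylated site.

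No paired analysis was possible because the files give no value per sample. For the same reason the stricter q of 0.001, the coverage minimums, the replicate counts and the omission of single replicates were not run, and other splits of the samples were not drawn. Joins of 200 or 5000 bp do not apply to gene lists. Depth is unknown and limits every listed difference.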

Other observations

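Outside the X chromosome, 11 of the 15 hypomethylated regions with at least 2 sites lay on autosomes, at loci named here after their values were seen. They included intergenic pairs of sites 367000 bp from Tshz3, a zinc finger transcription factor gene, and 15634 bp from Lyst, a lysosomal trafficking gene, with mean absolute differences of 39.0 and 36.8 percentage points in the authors' deposited table. Among developmental transcription factors outside the naming rule, Foxa2, a pioneer factor of endoderm, had 10 hypermethylated sites averaging 53.1 percentage points. The 228 hypermethylated sites of developmental transcription factors had a median distance of 17668 bp to the transcription start, 149 of them (65.4%) were intergenic and 7 lay in promoters.

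The draws of sites at equal list length were chosen after the result was seen. Hypermethylated sites had a listed same-strand neighbour of the same direction within 50 bp in 47.4% of cases (2975 of 6270), against 9.88% (48 of 486) of hypomethylated sites. The 48 include the 18 sites nearest G530011O06Rik. In 1000 random draws of 486 hypermethylated sites the median share was 6.58% (95% of draws between 3.70 and 10.1%). Drawing single sites at random separates neighbours by itself. The draws therefore cannot tell whether list length explains the difference between the full lists. The 57 CpGs listed as hypermethylated on both strands had a median gap of 8.29 percentage points between the strands' differences in the authors' deposited table. Pearson's r between the strands was 0.400 across these CpGs, which are not independent replicates and all lie above 25 percentage points. In the window of 100 genes on each side of Tet1 there were 58 hypermethylated and 4 hypomethylated sites, at the 63.0th percentile for all sites and the 52.4th for hypomethylated sites among 16865 such windows.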
